A study of Mus musculus with 12 samples.

How the data were processed

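Ribosome profiling measured footprints, the stretches of mRNA covered by ribosomes, in 8 libraries from mouse embryonic stem cells with dTAG-tagged eRF1: untreated and dTAG-13 treated (500 nM, 1 h), wild type and Gcn2 knockout, 2 biological replicates each. Poly(A) RNA was sequenced in 4 libraries, untreated and treated wild type, 2 replicates each. Per the labels, cells were grown with LIF and inhibitors of GSK3 and MEK, lysates were digested with RNase I, and footprints were taken from ribosomes isolated on sucrose gradients.

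The deposited values were raw counts per gene symbol, one column per library, in 1 table for footprints and 1 for RNA. Checked on the values, they are whole numbers with unequal library totals. The authors' processing notes name CASAVA 1.4, cutadapt, HISAT2 2.1.0 and the mm10 build. The counting tool, the annotation, the treatment of reads that fit several genes and whether footprints were counted over coding sequences or whole transcripts are not given in the sources used here. The footprint table held 22034 symbols, 5553 of them with 0 counts in all libraries, and the one for RNA held 49997, of which 22368 were at 0. Columns were matched to samples by genotype, treatment and replicate letter. The description of treated knockout replicate B repeats the column of replicate A, so its column was matched by the letter in its title alone, and values by letter for this group depend on that. Of the footprint symbols, 20050 were in the RNA table as written, 83 more were joined through synonyms in the RefSeq annotation of GRCm38, and 1901 (8.63%) were not joined.

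Totals ranged from 7874804 to 19691716 counts for footprints and from 17462458 to 24256097 for RNA. Replicates differed by more than counting error in each group. The chi-squared statistic per degree of freedom between the pair ranged from 3.05 to 26.1. The gene tests below included this extra spread as a dispersion per gene, shared by all groups of a fit. Differences in spread between groups were thus not modelled in the main fits, nor was spread common to many genes. With the other genotype left out, the genes called went from 599 to 19 in wild-type and from 1089 to 1893 in knockout cells. For translational efficiency the dispersion was shared between footprints and RNA. The common biological coefficient of variation was 0.116 for footprints and 0.0434 for RNA.

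Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10, library sizes were scaled by TMM, and a quasi-likelihood negative binomial model was fitted with robust dispersions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The 8 footprint libraries were fitted together by group (12267 genes, 4 residual degrees of freedom), and contrasts gave the treatment change in each genotype, the difference between these changes, and the untreated difference between genotypes. The 4 RNA libraries were fitted alone (15955 genes, 2 residual degrees of freedom). Translational efficiency was the interaction of assay and treatment over the 8 wild-type libraries (12887 genes), with TMM factors computed within each assay. SEs of log2 changes were derived from the change and its F statistic, and CPM are counts scaled by the TMM library sizes to a common total, as edgeR computes them. Replicate letters were not used as pairs, since no shared batch is named and there are only 2 of them per group.

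A total of 22 gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated one, with p adjusted over the lists of a comparison. The lists were ATF4 targets, stress mRNAs controlled by upstream open reading frames, aminoacyl-tRNA synthetases, termination and recycling factors, NMD factors, NMD-sensitive transcripts, ribosome rescue and quality control, polyamine and frameshift genes, selenoproteins, ribosomal proteins, other TOP mRNAs, replication-dependent histones, mitochondrially encoded mRNAs, immediate early genes, p53 targets, ER chaperones and unfolded protein response, heat shock genes, naive pluripotency, primed and early differentiation, primitive endoderm markers, two-cell-like markers and fibroblast markers. Lists with fewer than 4 tested members got no set test. Members are also counted as called over all genes tested and adjusted over the list alone.

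The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 8 genes with the largest rise and 8 with the largest fall among called genes with an average log2 CPM of at least 3 and, for comparisons of 2 groups, CPM that did not overlap, leaving out predicted genes, pseudogenes and mitochondrial RNAs. It added up to 4 called members per list with the smallest adjusted p, and always Etf1, Gspt1, Abce1, Eif2ak4, Atf4, Ddit3, Asns, Pelo, Oaz1 and Azin1. Where this gave more than about 30 genes, the text took the fixed genes, then members of the lists it describes, then the largest changes. The values of 2 genes that it took are not reported here.

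The alternatives chosen beforehand were relative log expression factors, DESeq2 1.42.0, no filter on low counts, replicate letter as a block, each library left out in turn, only the 4 libraries compared, TMM across assays, limma voom with quality weights, the estimated correlation, and, for the correlations across genes, only genes with an average log2 CPM of at least 5. Thinning all footprint libraries to the shallowest, a replicate block within genotype, and list tests without histones and ribosomal proteins were added after the data were seen. Scaling to mitochondrially encoded mRNAs was planned but not run, since these had 0 footprint counts. A relation to coding length was planned but not run, since coding lengths were not available.

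The pipeline was tested on simulated data with the depth of these libraries and a dispersion per gene shared by all groups of a fit. Of genes given a 2-fold change, edgeR recovered 62.7% in the wild-type and 67.2% in the knockout footprint contrast, 52.2% for the difference between genotypes, 70.1% for the untreated genotypes, 79.1% for RNA and 56.7% for translational efficiency. At 1.5-fold these shares were 23.9%, 30.3%, 10.6%, 30.3%, 58.5% and 14.9%. False calls were 5 of 122, 13 of 142, 9 of 96, 16 of 146, 10 of 163 and 10 of 107. A planted list of 40 genes was found in each contrast, and 0 of 20 unchanged lists were called by camera in each. Simulated genes varied independently of each other, so this does not test the list calls for genes that vary together. Differences in spread between groups and effects common to a replicate letter were not simulated. The shares and false calls above do not cover them. Figures were drawn with matplotlib 3.10.9.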

Results

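Ribosome footprints were counted in mouse embryonic stem cells of the line ES-E14TG2a whose release factor eRF1, the protein that recognises stop codons and ends translation, carries a dTAG degron. The compound dTAG-13 directs a ubiquitin ligase to proteins with this tag, which are then degraded. Cells were left untreated or given 500 nM dTAG-13 for 1 h, in a wild-type and in a Gcn2 knockout background. Gcn2, the product of Eif2ak4, is a kinase that phosphorylates the initiation factor eIF2 when amino acids are scarce or ribosomes stall. Each of the 4 footprint groups had 2 biological replicates, A and B, and poly(A) RNA was sequenced in treated and untreated wild-type cells only, again with 2 replicates each. There were 12 libraries in all. The labels name no vehicle control and no treated cells without the tag. Changes from the compound or its handling thus cannot be told apart from those that follow loss of eRF1, in footprints or in RNA.

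Untreated wild-type footprint libraries held 19691716 (A) and 17052771 (B) counts, and treated ones held 7874804 (A) and 14061463 (B). In the knockout, the untreated libraries held 17097802 (A) and 16573356 (B) counts and the treated ones 12333746 (A) and 15159178 (B). The RNA libraries held 24256097 (A) and 22005702 (B) counts without treatment and 23875157 (A) and 17462458 (B) with it. The log2 ratio between replicates had an SD across genes of 0.143 in treated knockout cells, the lowest of the footprint groups, and of 0.304 in untreated wild-type cells, the highest. Counts were compared as shares of a library, so a change in translation common to all mRNAs was not measured. Because dTAG-13 acts on the protein, the counts of Etf1 (eRF1; chromosome 18, 34902785 to 34932008 in mm10) do not measure its depletion. Their log2 change was 0.15 (SE 0.120, adjusted p = 0.552) in wild-type and 0.26 (SE 0.120, adjusted p = 0.201) in knockout cells.

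The first comparison asked which mRNAs gained or lost footprints after 1 h of dTAG-13 in wild-type cells. Atf4, the stress-response transcription factor whose mRNA is translated through upstream open reading frames when eIF2 is phosphorylated, rose 4.05-fold (log2 change 2.02, SE 0.157, adjusted p = 0.000121), from 76.0 ± 7.48 to 308 ± 74.9 CPM (counts scaled per library, as mean ± SD, n = 2 per group). Atf4 lies on chromosome 15 from 80255184 to 80257545. Histone mRNAs rose with it, among them H2ac7 by 4.06-fold (SE 0.235 in log2, adjusted p = 0.00133) and H2bc14 by 3.02-fold (SE 0.161, adjusted p = 0.000738). The subunit-joining GTPase gene Eif5b went from 33.9 ± 8.09 to 107.5 ± 6.23 CPM, and the ribosome assembly gene Pdcd11 rose 3.01-fold. The phosphate transporter gene Slc20a1 fell from 133 ± 22.2 to 41.2 ± 5.38 CPM (log2 change −1.70, SE 0.163, adjusted p = 0.000719).

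Further genes with the largest losses in wild-type cells were Nadk, which encodes NAD kinase (log2 change −1.54), the atypical protein kinase C gene Prkcz (−1.38), Cfap20dc (−1.37) and the palmitoyltransferase gene Zdhhc2 (−1.36). They were followed by the endocytic adaptor gene Sh3bp4 (−1.30), the phospholipid acyltransferase gene Agpat3 (−1.24) and Ivns1abp (−1.21). Among the largest gains were also H2bc22 (1.77) and H2bc7 (1.58). In all, 599 of 12267 genes tested passed, 361 rising and 238 falling. Among them, 70 of the risers and 29 of the fallers changed by over 2-fold. The count was 197 without untreated library A, 237 without treated library A, 334 without treated library B and 19 when the 4 wild-type libraries were fitted alone. It was higher, at 931, with the replicate letter as a block, 1048 without a filter on low counts, and 2109 with a block within genotype, a setting chosen after the data were seen. With the 4 wild-type libraries fitted alone, 38 genes of the naming rule lost their call. Fits without a single library still shared their dispersion with the knockout libraries. Of the 46 genes taken by the naming rule that passed, 24 did so without each library in turn. H2bc22 (log2 change 0.87 without treated library A) and Zdhhc2 (−1.03 without treated library B) were among those that did not, as were Ddit3, Gspt1, Pnrc2, Ppp1r15a, Vcp, Hbs1l, Aars, Rars, Rpl21, Selenok, Selenoh, Hnrnpa1, Ccng1, Upf1, Nbas, Odc1, Myc, Dppa2 and Lama1.

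The replication-dependent histones, made for packaging new DNA in S phase, stood out as a group. Of 58 measured in wild-type cells, 23 rose and none fell, and 36 rose when adjusted over the list alone. The median log2 change was 0.65 (camera adjusted p = 5.68e-27; adjusted p = 0.517 with an estimated correlation), or 0.42 without treated library A and 0.92 without treated library B. H1f5, a linker histone, rose 2.27-fold (SE 0.161). Histone genes are near-identical copies, and how reads shared between them were counted is not given in the sources used here. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, had a median change of 0.31 over 20 genes (adjusted p = 4.73e-06; adjusted p = 0.517 with an estimated correlation; 0.24 to 0.44 without each library in turn). Of these, 5 rose, or 9 adjusted over the list alone, including Lars (2.11-fold, SE 0.202; log2 change 1.08, or 0.69 without treated library A), Tars (1.63-fold, SE 0.115), Aars (1.52-fold, SE 0.131) and Rars (1.39-fold, SE 0.113).

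Stress mRNAs under the control of upstream open reading frames had a wild-type median change of 0.18 over 17 genes, with adjusted p = 0.00347 (adjusted p = 0.7 with an estimated correlation). Of these 6 rose, with 6 up and 1 down adjusted over the list alone. The risers included Atf4 and Ddit3, which encodes the transcription factor CHOP (log2 change 2.38, SE 0.488, adjusted p = 0.0177, 1.05 ± 0.775 to 5.90 ± 3.49 CPM). They also included the eIF2 phosphatase subunit gene Ppp1r15a (0.88, SE 0.199) and the decapping cofactor gene Pnrc2 (1.42, SE 0.274). This list's median was −0.05 without untreated library B (adjusted p = 0.155) and −0.02 without treated library A (adjusted p = 0.144), but 0.43 without treated library B. Ddit3 (1.67) and Pnrc2 (0.93) no longer passed without treated library A. Among 44 targets of ATF4, 2 rose, with 3 up and 1 down adjusted over the list alone (median 0.10, adjusted p = 0.244). The ATF4 target median passed upward without untreated library A (0.36, adjusted p = 2.1e-05) and without treated library B (0.325, adjusted p = 3.58e-05). It was as low as −0.21, short of the threshold, without treated library A. Asns, the asparagine synthetase gene and an ATF4 target, had a log2 change of 0.26 (SE 0.162, adjusted p = 0.428).

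Of 11 termination and recycling factors, 2 rose and 1 fell in wild-type cells (median 0.01, adjusted p = 0.584). Both genes for eRF3, the GTPase that works with eRF1, rose, Gspt1 by 1.74-fold (SE 0.144, adjusted p = 0.00797) and Gspt2 by 2.18-fold (SE 0.187, adjusted p = 0.00557). Without untreated library A the log2 change of Gspt1 was 0.63 and no longer passed. Eif2d, a factor of recycling and non-canonical initiation, fell 2.07-fold (SE 0.142, adjusted p = 0.00215). The recycling ATPase gene Abce1 had a change of 0.14 (SE 0.140, adjusted p = 0.666). Ribosome rescue and quality control genes gave 4 risers and 2 fallers of 29 (median 0.10, adjusted p = 0.18). The translation repressor gene Gigyf2 (1.08, SE 0.165), Nemf of the quality control complex (0.67, SE 0.119) and the unfoldase gene Vcp (0.74, SE 0.151) rose. Hbs1l, a partner of Pelo, fell (−0.61, SE 0.127), and the rescue factor gene Pelo itself had a change of 0.20 (SE 0.133, adjusted p = 0.465).

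The second comparison asked the same of Gcn2 knockout cells. Histone mRNAs gave most of the largest gains: H2ac7 rose 4.73-fold (SE 0.237 in log2, adjusted p = 0.000301), H2ac24 4.54-fold (SE 0.213) and H2ac6 3.97-fold (SE 0.211). Pnrc2 rose 5.37-fold (SE 0.281, adjusted p = 0.000395), to 16.2 ± 0.835 CPM (n = 2). Slc20a1 fell 4.68-fold (SE 0.167, adjusted p = 5.91e-05), and Sh3bp4 3.68-fold (SE 0.146). The cytoskeletal linker gene Msn fell 3.63-fold (SE 0.192), to 21.3 ± 1.15 CPM, and Ibtk, an mRNA with stress-responsive upstream reading frames, 3.49-fold (SE 0.151), to 15.5 ± 1.66 CPM. Atf4 had a log2 change of 0.30 (SE 0.154, adjusted p = 0.247; 97.4 ± 7.34 CPM treated against 78.9 ± 0.777 untreated).

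In the knockout, 1089 of the 12267 genes passed, 388 rising and 701 falling. Beyond 2-fold, 84 rose and 131 fell. The largest losses also included the casein kinase gene Csnk1g1 (−1.89), Zfp740 (−1.72), the ubiquitin ligase adaptor gene Kbtbd2 (−1.65) and the ESCRT gene Ubap1 (−1.63). The largest gains included H2bc14 (1.96) and H2bc22 (1.90). Among 44 ATF4 targets 1 rose and 3 fell (median −0.13, adjusted p = 0.184). The fallers were the tRNA exporter gene Xpot (−0.87, SE 0.113), the branched-chain aminotransferase gene Bcat1 (−0.92, SE 0.139) and Aldh18a1 (−0.79, SE 0.188). Ppp1r15a rose (0.84, SE 0.197), while the constitutive eIF2 phosphatase subunit gene Ppp1r15b fell (−0.90, SE 0.128), as did the tyrosyl-tRNA synthetase gene Yars (−1.04, SE 0.150). Of the 20 synthetases 3 rose in the knockout, Rars (0.52), Qars (0.55) and Eprs (0.51), and Yars alone fell. Ddit3 had a change of 1.19 (SE 0.469, adjusted p = 0.141). The count was 430 without untreated library A, 601 without untreated library B, 241 without treated library A and 215 without treated library B. It was 1893 when the 4 knockout libraries were fitted alone, 1658 without a filter and 3149 with a block within genotype. Of the 60 genes taken by the naming rule that passed, 29 did so without each library in turn. Among knockout calls given in this text, Ppp1r15a, Aldh18a1, H2bc22, Pabpc1, Tpt1, Gata4, Nes, Rars, Qars and Eprs passed in none of those 4 fits, and Rplp1, Hnrnpa1, Eef1b2, Oaz2, Selenoh, Selenow, Gpx1, Txnrd1, Tet2 and Eda2r in 1 to 3.

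Histones rose again as a group in the knockout: of 58, 36 rose and 2 fell, with 40 up and 2 down adjusted over the list alone. The median was 1.23 (adjusted p = 4.54e-44; adjusted p = 0.453 with an estimated correlation; 0.96 to 1.33 without each library in turn). The 2 that fell, named after their values were seen, were the linker histone gene H1f2 (−0.70) and H4c14 (−0.52). Ribosomal proteins had a median change of 0.49, and 33 of 82 rose, 61 adjusted over the list alone, with none falling (adjusted p = 7.79e-26; adjusted p = 0.595 with an estimated correlation). Among them, Rpl12 rose by 1.32 in log2 (SE 0.166), Rps20 by 1.14 (SE 0.148), Rpl21 by 0.98 (SE 0.125) and Rplp1 by 0.83 (SE 0.142). Other mRNAs with a 5′ terminal oligopyrimidine tract (TOP mRNAs), a motif shared with ribosomal protein mRNAs, had a median of 0.21 (adjusted p = 0.000463; adjusted p = 0.475 with an estimated correlation). Of 24, 4 rose, and 4 adjusted over the list alone: Hnrnpa1 (0.79), Eef1b2 (0.57), Pabpc1 (0.57) and Tpt1 (0.56). Their median was 0.13 without treated library A. The antizyme gene Oaz1, decoded by a programmed frameshift at a stop codon, rose 1.88-fold (SE 0.137, adjusted p = 0.00155) and Oaz2 2.07-fold (SE 0.183). The wild-type change of Oaz1 was 0.49 (SE 0.137, adjusted p = 0.0609). The antizyme inhibitor gene Azin1 had changes of 0.33 (adjusted p = 0.237) in wild-type and −0.30 (adjusted p = 0.236) in knockout cells.

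Selenoproteins, which read UGA as selenocysteine, had a knockout median of 0.23 (adjusted p = 0.0347; adjusted p = 0.595 with an estimated correlation). Of 21, 5 rose and 1 fell, or 8 up and 1 down adjusted over the list alone. Selenoh rose 2.20-fold (SE 0.202), Selenow 1.78-fold (SE 0.181) and Gpx1 1.49-fold (SE 0.135), and Txnrd1 fell 1.43-fold (SE 0.118). The list median was 0.43 without untreated library B, and the list no longer passed without untreated library A (adjusted p = 0.213) or without treated library B (adjusted p = 0.0553). In wild-type cells 2 of 21 selenoproteins rose, 3 adjusted over the list alone (median 0.13, adjusted p = 0.188). Of 82 ribosomal proteins 1, Rpl21, rose (1.46-fold, SE 0.124; list median −0.04, adjusted p = 0.785). That ribosomal protein median was 0.13 without untreated library A and 0.11 without treated library B, both past the threshold upward. It was −0.16 without untreated library B or treated library A, both past it downward. Of the other TOP mRNAs in wild-type cells 1 rose, Hnrnpa1, and 2 adjusted over the list alone (median 0.06, adjusted p = 0.189).

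**Figure D1:**
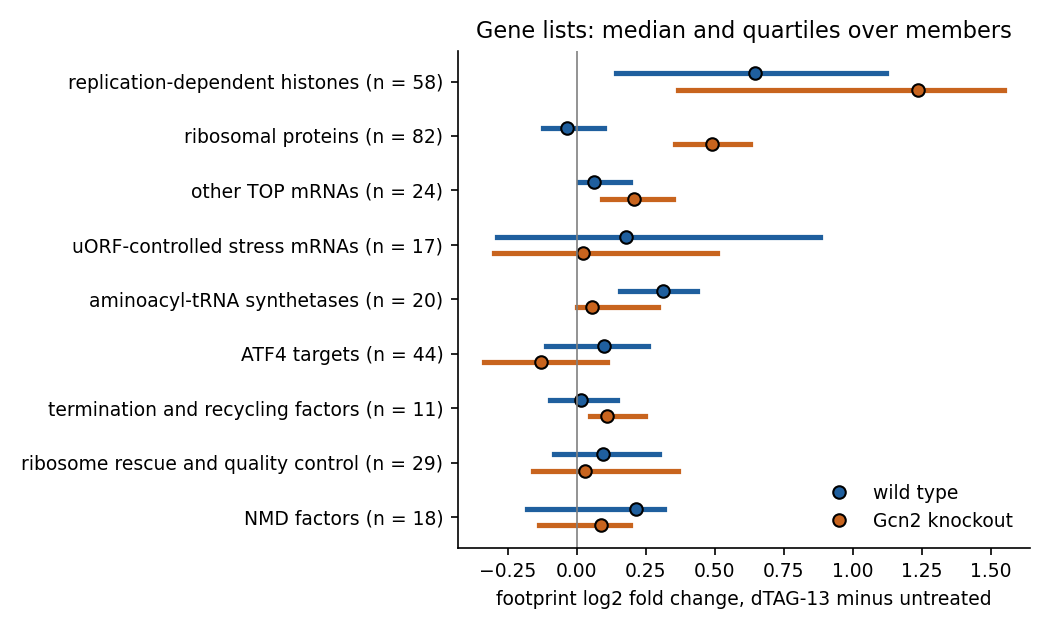
Median log2 change in footprints (dTAG-13 minus untreated; points) of each gene list in wild-type and Gcn2 knockout cells, with bars from the lower to the upper quartile of the members' changes. Histones lie highest in both genotypes, at 0.65 in wild-type and 1.23 in knockout cells, and ribosomal proteins lie at −0.04 in wild-type and 0.49 in knockout cells.

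The third comparison asked whether the response differed without Gcn2, as the knockout change minus the wild-type change. For Atf4 the difference was −1.71 (SE 0.217, adjusted p = 0.0165). Ibtk and Msn, which fell in the knockout, had wild-type changes of −0.19 (adjusted p = 0.506) and 0.18 (adjusted p = 0.645), and differences of −1.61 (SE 0.206, adjusted p = 0.0165) and −2.04 (SE 0.262, adjusted p = 0.0165). The purine synthesis gene Atic fell in the knockout (−0.91, SE 0.118), and the difference was −1.16 (SE 0.166, adjusted p = 0.0222). The ferritin heavy chain gene Fth1 rose in the knockout (1.53, SE 0.158) with a wild-type change of −0.04. The corepressor gene Tle5 rose in the knockout (1.05, SE 0.153) with a wild-type change of −0.46 (adjusted p = 0.115). Their differences were 1.57 (SE 0.221, adjusted p = 0.0222) and 1.51 (SE 0.218, adjusted p = 0.0222).

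These 6 genes were all that passed of 12267, with 1229 at an unadjusted p under 0.05. With edgeR, 0 genes passed without any single one of the knockout libraries, with 658 to 1561 at an unadjusted p under 0.05, and the 6 lost their calls in each of those fits. Leaving out wild-type libraries gave 4 genes without untreated library A, 32 without untreated library B, 3 without treated library A and 18 without treated library B. With all libraries, DESeq2 called 116, edgeR 39 with the replicate letter as a block, 192 without a filter and 733 with a block within genotype. Neither Ddit3 (−1.18, SE 0.685, adjusted p = 0.61) nor Gspt1 (−0.51, SE 0.203, adjusted p = 0.42) passed, nor did Oaz1 (0.42, SE 0.193, adjusted p = 0.493). These are values of the main fit. With a block within genotype, 3 genes of the naming rule that had not passed gained a call.

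**Figure D2:**
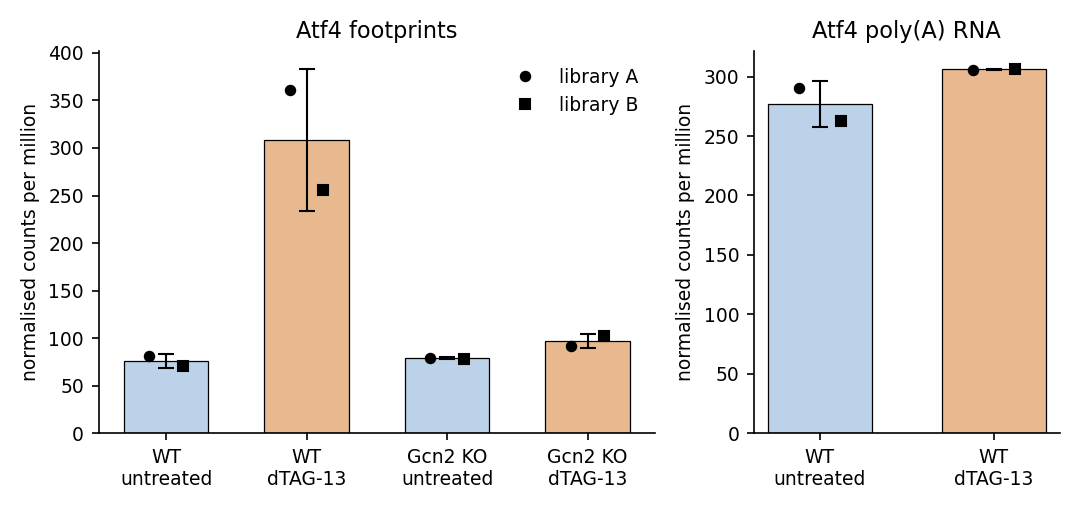
Atf4 level in CPM in each footprint and poly(A) RNA library; bars show the mean of 2 libraries, error bars the SD and points the libraries. Treated wild-type footprint libraries averaged 308 CPM against 76.0 untreated, and treated wild-type RNA averaged 306 CPM against 277 untreated.

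As a group, ribosomal proteins had the largest median difference of the lists, 0.55 (camera adjusted p = 2.52e-33, or 0.493 with an estimated correlation). Of 82 ribosomal proteins, 0 passed over all genes and 21 were higher adjusted over the list alone. Their median was 0.33 without treated wild-type library B and 0.70 without treated wild-type library A. Of 58 histones 0 passed, over all genes or adjusted over the list alone. Their median difference was 0.36 (camera adjusted p = 2.73e-06, or 0.66 with an estimated correlation). It was 0.09 without treated wild-type library B, where the list no longer passed (adjusted p = 0.21), and 0.62 without untreated knockout library B. Other TOP mRNAs had a median difference of 0.13 (camera adjusted p = 0.0177, or 0.493 with an estimated correlation), with 0 passing over all genes and 2 higher adjusted over the list alone. The list no longer passed in 5 of the 8 fits that left out a library, with medians down to 0.05 without treated knockout library A. ATF4 targets lay lower, with a median of −0.21 over 44 genes (camera adjusted p = 0.00193, or 0.66 with an estimated correlation). Of the 44, 0 passed over all genes and 2 were lower adjusted over the list alone. Upstream-reading-frame mRNAs lay at −0.12 over 17 genes, with a mean of −0.316 (camera adjusted p = 0.000609, or 0.493 with an estimated correlation). Of the 17, 2 passed as lower, Atf4 and Ibtk, and 4 adjusted over the list alone, so this list overlaps the single genes given above. Aminoacyl-tRNA synthetases lay at −0.16 over 20 genes (camera adjusted p = 0.00129, or 0.493 with an estimated correlation). Of the 20, 0 passed over all genes and 2 were lower adjusted over the list alone. None of these last 3 lists passed without untreated wild-type library B or treated wild-type library A, where the ATF4 target medians were 0.0034 and 0.10. Without treated wild-type library B their medians were −0.50, −0.46 and −0.33.

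Across the 12267 genes, which are not independent replicates, the changes of the 2 genotypes had a Pearson correlation of 0.455 and a Spearman correlation of 0.441. Of genes that passed in both, 113 rose in both (11.4 expected for independent lists), 153 fell in both (13.6 expected) and 2 moved in opposite directions. H2ac7 and Pnrc2 were among the shared risers and Slc20a1, Sh3bp4 and Eif2d among the shared fallers. Of the 599 genes that passed in wild-type cells, 575 had the same sign in the knockout. Without treated wild-type library B the Pearson correlation was 0.311.

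**Figure D3:**
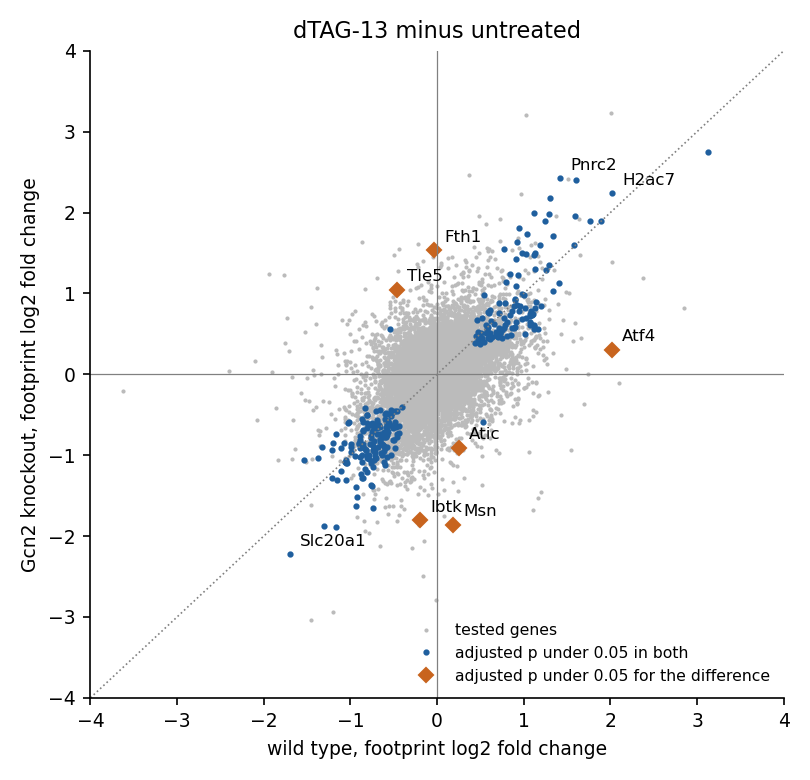
Log2 change in footprints (dTAG-13 minus untreated) in Gcn2 knockout cells against that in wild-type cells for each tested gene; blue points passed in both genotypes (268 genes). Orange diamonds mark the 6 genes whose change differed between genotypes, and 1 gene lies outside the axes. Atf4 lies far to the right of the diagonal, at 2.02 in wild-type and 0.30 in knockout cells.

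The fourth comparison asked how untreated knockout cells differed from untreated wild-type cells. Eif2ak4, the deleted gene (chromosome 2, 118388583 to 118475234), was 11.9-fold lower in the knockout (log2 difference −3.57, SE 0.223, adjusted p = 8.19e-06), at 2.40 ± 0.0919 against 28.6 ± 1.19 CPM (n = 2 per group). It was the single gene of 12267 that passed, or 1 of 31 with DESeq2, of 14 with the replicate letter as a block and of 113 without a filter. Atf4 differed by 0.05 (SE 0.153, adjusted p = 0.965), Asns by 0.02 (adjusted p = 0.99) and Gspt1 by 0.24 (adjusted p = 0.831). As groups, ER chaperones and unfolded protein response genes lay higher in the knockout, with a median of 0.41 over 23 genes and 7 higher adjusted over the list alone (adjusted p = 1.57e-16; adjusted p = 0.476 with an estimated correlation). So did p53 targets, with a median of 0.41 over 26 genes and 6 higher adjusted over the list alone (adjusted p = 3e-11; adjusted p = 0.476 with an estimated correlation). Ribosomal proteins lay lower, with a median of −0.22 over 82 genes and 2 lower adjusted over the list alone (adjusted p = 1.13e-13; adjusted p = 0.857 with an estimated correlation). Other TOP mRNAs lay at −0.16 (adjusted p = 4.02e-05; adjusted p = 0.476 with an estimated correlation). The ribosomal protein median was −0.07 without untreated wild-type library A, where the list no longer passed (adjusted p = 0.16), and −0.36 without untreated wild-type library B. The ER list median was 0.19 without untreated knockout library A and 0.63 without untreated knockout library B, and the other TOP median −0.09 without untreated knockout library A. The p53 list median was 0.21 without untreated wild-type library B and 0.70 without untreated wild-type library A.

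The fifth comparison asked which mRNAs changed in level in wild-type cells. The matricellular genes Ccn2 and Ccn1 rose 1.78-fold (SE 0.0789 in log2, adjusted p = 3.34e-11) and 1.68-fold (SE 0.0762, adjusted p = 3.86e-10). The AP-1 genes Jun (1.75-fold, SE 0.151, adjusted p = 0.00336) and Junb (1.56-fold, SE 0.0834, adjusted p = 5.43e-07) and the MAP kinase feedback gene Spry4 (1.71-fold, SE 0.0801, adjusted p = 1.8e-09) rose too. So did Phlda1 (1.57-fold), Zfp819 (1.43-fold) and the YAP inhibitor gene Amotl2 (1.55-fold, SE 0.0541, adjusted p = 1.02e-12). Immediate early genes, transcribed soon after a stimulus, rose as a group, with 6 of 30 rising, 14 adjusted over the list alone, and a median of 0.22 (adjusted p = 1.98e-37; adjusted p = 0.197 with an estimated correlation). The helicase gene Ddx39b (−0.75), the glypican gene Gpc2 (−0.63) and Zbtb14 (−0.44) fell. Of 13 mitochondrially encoded mRNAs, COX2 (−0.54) and ND6 (−0.24) fell (median −0.12, 2 adjusted over the list alone, camera adjusted p = 0.0166, or 0.68 with an estimated correlation).

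Atf4 mRNA changed by 0.14 (SE 0.0482, adjusted p = 0.622), from 277 ± 19.5 to 306 ± 0.330 CPM, and Ddit3 mRNA by 0.33 (SE 0.169, adjusted p = 0.939). In all, 26 of 15955 genes passed, 19 rising and 7 falling, and 8 passed with DESeq2. The count was 267 without untreated library B, 14 without treated library A and 16 with the replicate letter as a block. Among the named genes, Ccn1, Ccn2, Spry4, Junb, Phlda1 and Amotl2 passed without each library in turn. Jun did not without treated library A (adjusted p = 0.0778), and each named faller and Zfp819 failed in at least 2 of the 4 such fits. The change of Ddx39b ranged from −1.06 to −0.45 over them. With DESeq2, Ccn1, Ccn2, Spry4, Junb and Amotl2 kept their calls, and Phlda1, Jun, Zfp819 and each named faller lost theirs. The mitochondrial list median was 0.05 without untreated library B (adjusted p = 0.321) and −0.06 without treated library A (adjusted p = 0.437).

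The last comparison asked how far footprints moved beyond mRNA level in wild-type cells, here called a change in translational efficiency. Footprints count ribosomes on an mRNA, moving or held, so this ratio does not by itself measure protein output. Atf4 rose 3.65-fold relative to its mRNA (log2 change 1.87, SE 0.208, adjusted p = 0.00602), Eif5b 3.17-fold (SE 0.190, adjusted p = 0.00602) and Pdcd11 2.91-fold (SE 0.245). Other large gains were those of the nuclease gene Fan1 (1.44), the microtubule polymerase gene Ckap5 (1.36), the talin gene Tln1 (1.32) and Thoc2l (1.27). Slc20a1 fell 3.37-fold (SE 0.175, adjusted p = 0.00602), Nadk 2.94-fold (SE 0.149, adjusted p = 0.00602) and Sh3bp4 2.54-fold (SE 0.146). They were followed by Prkcz (−1.33), Cfap20dc (−1.30), Agpat3 (−1.29), the tubulin-modifying enzyme gene Ttll1 (−1.27) and the innate immune kinase gene Ripk2 (−1.26). Gspt1 (0.79, SE 0.161), Gspt2 (1.21, SE 0.195), Gigyf2 (1.05, SE 0.205) and Nemf (0.66, SE 0.123) rose. Eif2d (−1.08, SE 0.158), Rnf14 (−0.67, SE 0.140) and Ei24 (−1.06, SE 0.136) fell.

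Of 12887 genes, 190 passed for translational efficiency, 101 rising and 89 falling. Aminoacyl-tRNA synthetases had a median of 0.27 over 20 genes, with 1 rising, Tars, and 5 adjusted over the list alone (adjusted p = 0.000165; adjusted p = 0.602 with an estimated correlation). Upstream-reading-frame mRNAs had a median of 0.17 over 17 genes, with 1 rising, Atf4, and 6 up and 1 down adjusted over the list alone (adjusted p = 0.00995; adjusted p = 0.602 with an estimated correlation). The second list no longer passed without untreated footprint library B (adjusted p = 0.155) or treated footprint library A (−0.08, adjusted p = 0.0884), but its median reached 0.69 without treated footprint library B. That of the first ranged from 0.20 to 0.40. Across 11558 genes the footprint and mRNA changes had a Pearson correlation of 0.0532 and a Spearman correlation of 0.0801. Between them, 4 genes rose in both (0.479 expected). With edgeR 0 genes passed for translational efficiency without any single one of the RNA libraries, with 1191 to 1284 at an unadjusted p under 0.05. Of the 4 fits without a footprint library, Fan1 passed in 0, Ripk2 in 1, Prkcz and Ttll1 in 2, and Cfap20dc, Thoc2l, Gspt1, Gigyf2, Rnf14 and Tars in 3. The count was 671 without untreated footprint library B. With all libraries DESeq2 called 435, and edgeR 459 without a filter and 1561 with the replicate letter as a block. Histone mRNAs, which lack poly(A) tails, made up 0.00352% to 0.00451% of the poly(A) RNA counts, so their translational efficiency was not informative.

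The remaining lists did not pass in either treated genotype with all libraries. NMD factors had medians of 0.22 in wild-type (3 rose and 1 fell of 18; adjusted p = 0.121) and 0.09 in knockout cells (1 rose and 1 fell; adjusted p = 0.627). Upf1 (0.45) and Nbas (0.69) rose in wild-type cells. Transcripts sensitive to nonsense-mediated decay had medians of 0.18 (adjusted p = 0.18) and 0.11 (adjusted p = 0.405). Polyamine and frameshift genes had a wild-type median of −0.04 with a mean of 0.06 (adjusted p = 0.875; −0.19 to 0.12 without each library in turn), Odc1 falling (−0.72, or −0.44 to −1.08), and a knockout median of 0.09 (adjusted p = 0.178). Immediate early genes had footprint medians of 0.0051 (−0.13 to 0.21, adjusted p = 0.785; Myc rose by 1.29) and 0.0043 (adjusted p = 0.837). For p53 targets the medians were −0.11 (adjusted p = 0.189; Ei24 and Ccng1 fell, by 1.13 and 0.83) and −0.11 (adjusted p = 0.184; Eda2r fell by 1.33). The p53 target median passed downward without untreated wild-type library B (−0.22, adjusted p = 0.000896) and without treated wild-type library A (−0.29, adjusted p = 0.00141), yet was 0.18 without untreated wild-type library A. It also passed without untreated knockout library B (−0.24, adjusted p = 0.022). Lists that passed upward without treated wild-type library B were NMD factors (0.26, adjusted p = 0.00663), NMD-sensitive transcripts (0.19, adjusted p = 0.00988) and selenoproteins (0.21, adjusted p = 0.0322). NMD-sensitive transcripts did so without untreated wild-type library A too (0.25, adjusted p = 0.00981), and polyamine and frameshift genes without untreated knockout library B (0.25, adjusted p = 0.0481). ER chaperones had medians of 0.09 (adjusted p = 0.982) and −0.02 (adjusted p = 0.988; 0.25 without untreated knockout library A and −0.26 without B, both past the threshold), and heat shock genes of 0.14 (0.01 to 0.13 without each library in turn, adjusted p = 0.322) and −0.04 (−0.10 to 0.03, adjusted p = 0.837). In the knockout, termination factors (median 0.11, 0 up and 1 down of 11, camera adjusted p = 0.837) did not pass either. Nor did ribosome rescue genes (0.03, 3 up and 3 down of 29, adjusted p = 0.694) or aminoacyl-tRNA synthetases (0.06, 3 up and 1 down, adjusted p = 0.554). Upstream-reading-frame mRNAs did not pass as a list (median 0.02, mean 0.10, with the test pointing down, camera adjusted p = 0.837). Their response was mixed, with 4 up and 3 down of 17, or 5 up and 4 down adjusted over the list alone. Further medians in this paragraph also moved when a library was left out, some with a change of sign.

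Cell identity lists did not pass in either treated genotype with all libraries. Naive pluripotency genes had medians of 0.03 in wild-type (adjusted p = 0.189; L1td1 and Dppa2 rose, by 0.77 and 0.55) and −0.01 in knockout cells (adjusted p = 0.837; Tet2 fell by 0.65), and primed and early differentiation genes of 0.18 (0.04 to 0.24 without each library in turn, adjusted p = 0.284; Nes rose by 0.81) and 0.17 (adjusted p = 0.405; Nes rose by 0.48, or 0.31 to 0.58). The naive list passed upward without untreated wild-type library A (0.14, adjusted p = 0.0413) and without treated wild-type library B (0.22, adjusted p = 0.00988). Primitive endoderm markers had medians of 0.31 (−0.07 to 0.39 without each library in turn, adjusted p = 0.293; Lama1 rose by 0.53) and −0.22 (adjusted p = 0.903; Gata4 fell by 1.17), and fibroblast markers of 0.27 (−0.21 to 0.51, adjusted p = 0.602) and 0.16 (adjusted p = 0.837), over 12 and 7 genes. Of the two-cell-like markers fewer than 4 were measured, too few for a set test. Mitochondrially encoded mRNAs had no footprint counts. No call of the 22 lists in any comparison held with an estimated correlation, where the lowest adjusted p was 0.197.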

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

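The tests of depth, mRNA level and single libraries for Atf4, of the starting level for ribosomal proteins and of the histone sum were chosen only after the result was seen. Each item in this part stands here because the change after dTAG-13 differed between wild-type and Gcn2 knockout cells by the test of that difference (knockout minus wild type), and the histone pattern is weighed as well because histones had the largest list median in both genotypes.

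The Atf4 difference was −1.71 (SE 0.217). With all footprint libraries thinned to the shallowest it was −1.78. Atf4 has many counts at that depth, and thinning leaves the shallowest, treated wild-type library A, as it is. This test could thus hardly move the difference and decides nothing about that library. Atf4 mRNA in treated wild-type cells changed by 0.1446, 11.4 combined SE below the footprint change, which argues against a rise in mRNA there. Without each library in turn the difference stayed between −1.98 and −1.444, which argues against a single library carrying it, although the adjusted p ranged from 0.00104 to 0.236 and missed the threshold without each knockout library. A candidate explanation is that the Atf4 response needs Gcn2, consistent with the direction of the difference; other differences between the cell lines than Gcn2 were not tested, and RNA from knockout cells was not analysed here.

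Ribosomal proteins differed by a median of 0.553 (other TOP mRNAs by 0.131). In treated cells alone the knockout lay above wild type by a median of 0.329 (camera adjusted p = 7.03e-14; adjusted p = 0.464 with an estimated correlation), which argues against a low starting level in untreated knockout libraries as the whole cause. Library spread cannot be told apart from a response to treatment: pairing libraries by letter, the lowest knockout change lay 0.327 above the highest wild-type change, more than the largest difference between replicates (0.292), but over all pairings the gap was 0.0618. Ribosomal protein genes have many processed pseudogenes, and whether shared reads may add to the pattern was not tested. Short proteins, a list drawn up after the data were seen, lay above wild type by a median of 0.299 in treated cells alone. Their changes differed between genotypes by a median of 0.231. A gain on short coding sequences in general could thus contribute, and this was not tested. With an estimated correlation the ribosomal protein list did not pass, so a higher share of ribosomal protein footprints in treated knockout cells is a hypothesis only.

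Replication-dependent histones differed by a median of 0.363, and their footprints rose in both genotypes. The sum over all 66 histone genes changed by 0.431 (SE 0.167, edgeR adjusted p = 0.175) in wild-type and by 0.512 (SE 0.167, edgeR adjusted p = 0.0761) in knockout cells, but by 0.185 (SE 0.178) without treated wild-type library A and by 0.377 (SE 0.205) without untreated knockout library A, so reads moving between copies remain open as a cause. S phase genes had a median of −0.00932 in wild-type RNA (−0.00994 to 0.00416 without each library in turn). This argues against a larger share of cells in S phase in wild-type cells only as far as mRNA levels show it within 1 h. In wild-type footprints the S phase genes passed as a list (8 rose and none fell, median 0.139, camera adjusted p = 0.000647, or 0.307 with an estimated correlation). In knockout footprints their median was 0.0841 (0.00734 to 0.0959, camera adjusted p = 0.325). Short proteins had a wild-type median of 0.0398 (−0.0539 to 0.146 without each library in turn, against 0.42 to 0.917 for histones), which argues against a gain on all short coding sequences as the whole cause in wild-type cells; in the knockout they had 0.296, so that this could contribute there. Histone mRNA levels could not be read from poly(A) RNA, so a rise of the histone mRNAs themselves remains open. Beyond the share of cells in S phase and the treatment itself, no biological explanation was tested for the rise.

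The remaining items are given as values. The difference was −1.61 for Ibtk, −2.04 for Msn, 1.57 for Fth1, −1.16 for Atic and 1.51 for Tle5. Median differences were −0.212 for ATF4 targets, −0.12 for upstream-reading-frame mRNAs, which include Atf4 and Ibtk, and −0.163 for aminoacyl-tRNA synthetases.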

How the results depend on the processing

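Of these alternatives, thinning to the shallowest library, the block within genotype and the list tests without histones and ribosomal proteins were chosen only after the results were seen. No called gene changed sign in any alternative, and of 2319 values of named genes under alternatives 1911 kept their side of the threshold (25 of them not called and with a changed sign), 386 lost their call and 22 gained one; for lists these were 1040 (90 with a changed sign), 42 and 48 of 1139, and 9 passed with the opposite sign. Relative log expression factors gave 599 wild-type, 1098 knockout, 6 difference, 1 genotype, 25 RNA and 183 efficiency genes. DESeq2 gave 806, 1192, 116, 31, 8 and 435, and the absence of a filter 1048, 1658, 192, 113, 34 and 459. DESeq2 left 3805, 2854, 5708, 1190, 0 and 4747 genes without an adjusted p, so its counts are not over the same genes. For efficiency, TMM across assays gave 183 genes and limma voom with quality weights 278, which kept 173 of the 190 and lost 5 named genes. The 4 libraries compared, fitted alone, gave 19 wild-type, 1893 knockout and 1 genotype genes, and thinning gave 555, 942, 8 and 3. The replicate letter as a block gave 931, 1564, 39, 14, 16 and 1561 genes, and within genotype 2109, 3149 and 733; the correlation across genes of A minus B was 0.651 between untreated and treated wild-type libraries, 0.173 in the knockout and −0.00108 in RNA, and no shared batch is named. Leaving out each library in turn gave 197 to 659 wild-type, 215 to 601 knockout, 0 to 32 difference, 1 to 10 genotype, 14 to 267 RNA and 0 to 671 efficiency genes; these fits leave groups of 1, whose library is assumed to vary like the others. The counts of 0 came from edgeR without a knockout library (658 to 1561 genes at an unadjusted p under 0.05) and without an RNA library (1191 to 1284). The Pearson correlation of the genotypes was 0.311 to 0.451 without a library and 0.565 at an average log2 CPM of at least 5, and that of footprints and mRNA 0.0224 to 0.0629 and 0.169. For lists, the sign here and in the counts above is the direction given by camera. Lists that passed in the direction opposite to that with all libraries did so without 1 library. Ribosomal proteins did so in wild-type footprints (medians −0.164 to 0.133, and 0.108 without treated library B) and in RNA (−0.0595 to 0.0473). In efficiency their medians were −0.183 to 0.120, and 0.0968 without treated footprint library B. ER chaperones did so in the knockout (−0.259 to 0.248) and in the difference (−0.293 to 0.183). Between untreated genotypes, ATF4 targets (−0.146 to 0.299) and histones (−0.314 to 0.106) did so. The ATF4 target median was −0.0181 with all libraries, with camera pointing up, and −0.146 in the opposite fit. In wild-type footprints the ribosomal protein list level changed by −0.0464 between the A libraries and by −0.0198 between the B libraries. A fit without 1 of them compares unequal sets of letters, so its median also holds the difference between letters. Causes of the changed signs were otherwise not tested. Scaling to mitochondrially encoded mRNAs was not run, since these had no footprint counts. Depth and spread limit small effects: at 1.5-fold, 10.6% of simulated differences between genotypes were recovered, with a spread shared by all groups.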

Other observations

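The lists of long and short proteins and of YAP and serum response targets were drawn up after the data were seen, and the test of protein length in wild-type cells was chosen only after the result was seen; those of length between genotypes and of the YAP list without the genes that prompted it were written down before their results.

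Textbook long proteins, such as those of the cytoskeleton and of motor and ubiquitin ligase complexes, were frequent among the genes that rose in wild-type footprints. Of 125 long proteins, 48 rose and 4 fell, with a median log2 change of 0.433 (quartiles 0.237 and 0.712; camera adjusted p = 8.32e-29; adjusted p = 0.181 with an estimated correlation), against 0.0398 for 127 short proteins (−0.0539 to 0.146 without each library in turn). Since the long proteins were listed after some were seen among these risers, this rise decides nothing about length. In the knockout the long-protein median was 0.203, with 22 up and 14 down (adjusted p = 0.0161; adjusted p = 0.577 with an estimated correlation; 0.128 to 0.343 without each library in turn, with an unadjusted p = 0.629 without untreated library B), and the short-protein median 0.296 (adjusted p = 2.98e-12; adjusted p = 0.29 with an estimated correlation; 0.218 to 0.344). Long proteins differed between the genotypes by a median of −0.3 (adjusted p = 4.27e-15; adjusted p = 0.303 with an estimated correlation) and short ones by 0.231 (adjusted p = 2.87e-10; adjusted p = 0.303 with an estimated correlation). The long-protein difference holds the same wild-type change, so it is partly fixed by how the list was drawn up. Without each library in turn it ranged from −0.386 to −0.189 and the short-protein one from 0.0990 to 0.302. Whether the change after dTAG-13 goes with protein length is left open. With an estimated correlation none of these lists passed, coding lengths were not available for a test over all genes, and the long-protein mRNAs themselves had a median of 0.0621 in wild-type RNA (−0.0122 to 0.139).

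Of the mRNAs that rose in wild-type cells, Ccn1, Ccn2, Amotl2 and Ajuba are known targets of the coactivator YAP, Ajuba being named after its values were seen. The list of 26 YAP and serum response targets, with 4 rising and 8 adjusted over the list alone, had a median RNA change of 0.121 (adjusted p = 3.48e-19; adjusted p = 0.0472 with an estimated correlation), which decides nothing, since the list was drawn up after these 4 were seen to rise and includes them. Without the 4 genes the other 22, with 0 rising and 1 adjusted over the list alone, had a median of 0.0917 (adjusted p = 0.000422; adjusted p = 0.141 with an estimated correlation). A rise of this class of mRNAs as a group is thus a hypothesis, which passed at the preset correlation and not at the estimated one. The 24 members measured in footprints had medians of 0.0641 in wild-type and 0.151 in knockout cells, neither past the threshold (adjusted p = 0.117 and 0.263).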
